A study of Homo sapiens with 21 samples.

How the data were processed

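Gene expression was measured in 3 human acute myeloid leukaemia cell lines, MOLM-14, U937 and HL-60, on Affymetrix HT HG-U133A arrays, which read each transcript with sets of short probes (probe sets). Per the labels, each line was transduced with a short hairpin RNA against luciferase (shLuc), a target absent from human cells, or with either of 2 hairpins against SYK (shSYK_1 and shSYK_2). Puromycin at 1 µg/ml was applied from 48 h after infection and total RNA was taken at day 5. The 21 arrays fell into 9 groups, with 3 shLuc arrays and 2 arrays for each SYK hairpin in every line. The labels describe the replicates as separate transductions. All came from the same 3 lines, so the p-values measure the spread between transductions of these lines and do not reach beyond them.

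The deposited table held 1 intensity value per probe set and array, made by the authors with RMA, per the submitters' processing notes (version not given). RMA corrects the background, brings all arrays to one distribution of values and summarises the probes of a set. The image analysis and other upstream steps are not given in the sources used here. The planned tests assumed values on the log2 scale. The deposited intensity values ran from 3.23 to 13024.67, a linear scale, so log2 was taken here before every test, without a pseudocount. RMA gives no detection call and compresses fold changes, most of all at low intensity, so a printed fold can understate the change in RNA. The median intensity of the arrays ranged from 18.4 to 20.6, and the precision is limited by the number of arrays. The upper quartile was 122.3 on HL-60 shSYK_2 replicate 1 and 134.49 to 139.77 on the other arrays. No further normalisation was applied to the deposited intensity values in the reported results.

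The table held 22277 probe sets. Of these, 62 were Affymetrix controls, 19730 carried 1 gene symbol in the platform annotation, 568 carried several and 1979 carried none in the annotation used. Symbols were updated by gene ID through the RefSeq gene table of GRCh38.p14 for 19713 probe sets, and 17 kept the name of the platform annotation. That table was used for names alone and no coordinates were taken from it, because no genome build is given for the array values. Controls and probe sets with several symbols or none were left out of the tests. Each gene was represented by its probe set with the highest mean over all arrays, which gave 12165 genes. Probe sets of near-identical genes, such as FCGR2A and FCGR2B, ANXA2 and its pseudogenes, histone H2A genes or HLA genes, can bind transcripts of both, and their gene assignment is uncertain.

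One linear model with a mean for each of the 9 groups was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes). It had 12 residual degrees of freedom and 4.09 prior degrees of freedom. Contrasts compared the mean of both SYK hairpin groups with shLuc within each line and averaged over the 3 lines. Further contrasts took the MOLM-14 response minus the mean of the U937 and HL-60 responses, shSYK_2 minus shSYK_1, and each hairpin against shLuc in each line. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called. Throughout, a gene rose or fell where it was called. A log2 change is a difference of group means.

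Gene groups were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 26 lists within each of 5 contrasts. Of the lists, 5 held markers of other cell types (erythroid, megakaryocyte, T and NK, B, and epithelial or stromal cells). The list of SYK signalling components held SYK itself, the target of the hairpins, and FLT3, and was not tested without them. The lists held 568 different genes, of which 498 were measured, and 7 measured genes belonged to more than 1 list. List members not represented in the tested set were not analysed here. Each list was also counted gene by gene, over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry, which tests each list by itself and not against the other genes, were alternatives. Camera for single hairpins and for the difference between hairpins was added after the data had been seen.

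The comparisons, gene lists, processing alternatives and the rule for the genes named in the text were fixed before the data were examined. SYK, FLT3 and MYC were named in every comparison. For the average of the lines, the rule took up to 12 called genes with the largest rise and 12 with the largest fall among those with the same sign in all 6 hairpin effects. For each line it took 10 and 10 with the same sign for both hairpins. For the line difference and the hairpin difference it took 8 and 8. For each called list it took the 4 members with the smallest p. Other genes named in the closing section were chosen after their values were seen.

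For 1 array, HL-60 shSYK_2 replicate 1, the labels conflict. Its title and treatment name shSYK_2 and its source text names shSYK_1. It was kept as shSYK_2, and the other assignment was run as an alternative. A check in the closing section, chosen after the data had been seen, excluded shSYK_1 cells on this array. Calls lost under that alternative thus rest on an assignment that the array's values go against. Further alternatives were the mean of a gene's probe sets, every probe set tested on its own, quantile normalisation and median centring of the arrays, removal of the dimmest 40% of genes, a trended and robust prior, array weights, models of 1 line alone, a block for replicate number, a minimum absolute log2 change of 0.5 and the omission of each array in turn. Dixon's test of single outlying arrays was not run on these groups of 2 or 3 arrays. The 15 pairs of replicate arrays correlated at 0.993 to 0.998. The lowest was the HL-60 shSYK_2 pair, and the next lowest stood at 0.9969 (MOLM-14 shSYK_1). At most 138 probe set values were identical between 2 replicate arrays, so all were kept as separate replicates.

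The procedure was tested on simulated data in which 50 genes were changed at each of several sizes. For the average of the lines, it called 74% of genes changed by 0.25 log2 and 98% of those changed by 0.5, with 8 false calls among the 12165 genes run. Within a line it called 10% (MOLM-14), 12% (U937) and 6% (HL-60) of genes changed by 0.25, and 78%, 78% and 80% of those changed by 0.5, with 8, 3 and 9 false calls. A list shifted by 0.2 log2 was called, and 0 of the other lists were. The simulated genes varied independently, so this run could not show false list calls that come from correlation between genes. Because both hairpins of a line are compared with the same shLuc arrays, agreement between them was set beside 100 simulations of unchanged groups. Group labels were redrawn in 100 splits of the arrays within lines, the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.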

Results

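RNA of 3 human myeloid leukaemia lines was profiled 5 days after infection with hairpins against SYK, a cytoplasmic tyrosine kinase that signals downstream of immune receptors and integrins. MOLM-14 is a monocytic line known to carry an internal tandem duplication of the receptor tyrosine kinase FLT3, U937 is a monocytic line from a histiocytic lymphoma and HL-60 is a promyelocytic line. Each line had 3 arrays with the luciferase control hairpin shLuc and 2 arrays each with shSYK_1 and shSYK_2, 21 arrays in all, and 12165 genes were tested. The series concerns SYK as a regulator of FLT3, so SYK was examined first, and FLT3 and MYC were followed in every comparison.

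SYK RNA was lower on every SYK hairpin array than on every shLuc array of the same line. In MOLM-14 the mean log2 intensity of SYK, on the brighter of its 2 probe sets, was 8.45 ± 0.0350 (SD, n = 3) with shLuc, 6.16 ± 0.00618 (n = 2) with shSYK_1 and 5.49 ± 0.192 (n = 2) with shSYK_2. In U937 it was 8.68 ± 0.0210 (n = 3), 6.999 ± 0.0361 (n = 2) and 6.56 ± 0.0134 (n = 2). In HL-60 it was 8.99 ± 0.0744 (n = 3), 7.02 ± 0.0245 (n = 2) and 6.78 ± 0.171 (n = 2). Relative to shLuc, 16.2% of the SYK intensity remained in MOLM-14, 26.7% in U937 and 23.5% in HL-60. The average log2 change over the lines was -2.21 (SE 0.0394, limma adjusted p = 8.95e-16). The second SYK probe set changed by -1.95 in MOLM-14, -1.88 in U937 and -1.92 in HL-60, from lower starting intensities. On the brighter probe set SYK fell further with shSYK_2 than with shSYK_1, by -0.45 log2 on average (SE 0.0516, limma adjusted p = 2.94e-06), although HL-60 alone did not pass (-0.24, limma adjusted p = 0.0716). The HL-60 value passed without HL-60 shSYK_2 replicate 2 (-0.36, limma adjusted p = 0.0118), without either MOLM-14 shSYK_2 array (0.0451) and with the dimmest 40% of genes left out (0.0386). On the second probe set the hairpins differed by -0.15 on average (limma adjusted p = 0.0339 over all probe sets) and by 0.11 in HL-60 (0.450).

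MYC, a transcription factor that drives growth genes, fell with shSYK_1 in all 3 lines. FLT3, a receptor tyrosine kinase of blood progenitors, fell with shSYK_1 in MOLM-14 and HL-60, and its call in U937 was marginal. With shSYK_2, FLT3 passed the test in 0 of 3 lines, and MYC fell in HL-60 and did not pass the test in MOLM-14 or U937. FLT3 changed by -0.84 in MOLM-14, -0.45 in U937 and -0.90 in HL-60 with shSYK_1, and by 0.14, -0.22 and -0.03 with shSYK_2. The difference between the hairpins was 0.69 log2 averaged over the lines (SE 0.0918, limma adjusted p = 1.40e-05). Pooled over both hairpins, FLT3 fell by 0.38 on the log2 scale on average (limma adjusted p = 3.80e-04) and fell in HL-60 (-0.47, limma adjusted p = 0.00908). The pooled values of -0.35 in MOLM-14 (limma adjusted p = 0.0556) and -0.33 in U937 (0.0796) did not pass the test. MYC changed by -0.92, -0.75 and -0.87 with shSYK_1 and by -0.14, -0.14 and -0.56 with shSYK_2 in MOLM-14, U937 and HL-60, and differed between hairpins by 0.57 (SE 0.0436, limma adjusted p = 3.29e-08). Averaged over the lines, MYC fell with shSYK_2 too (-0.28, limma adjusted p = 4.66e-05), and pooled over both hairpins it fell in all 3 lines (-0.53, -0.44 and -0.71). Neither gene passed the test of a difference between MOLM-14 and the other lines (FLT3 0.05, limma adjusted p = 0.896, and MYC 0.05, limma adjusted p = 0.777). In U937, FLT3 lay near the lowest intensities of the arrays, at a mean log2 of 4.48 ± 0.372 (SD, n = 3) with shLuc. Its U937 change with shSYK_1 (limma adjusted p = 0.0441) was -0.24 without U937 shLuc replicate 3 (limma adjusted p = 0.144), where the pooled U937 value was -0.13, and its call was lost without any 1 of 15 single arrays. With a trended and robust prior, MYC passed with shSYK_2 in MOLM-14 (limma adjusted p = 0.0317) and U937 (0.0371). The pooled HL-60 value of FLT3 did not pass the test without HL-60 shLuc replicate 2 (-0.40, limma adjusted p = 0.0514). With HL-60 shSYK_2 replicate 1, whose labels conflict, placed in shSYK_1, this FLT3 value was -0.30. The closing section excludes shSYK_1 cells on that array. The pooled MOLM-14 value passed under several settings, among them a model of the MOLM-14 arrays alone (limma adjusted p = 0.0117). The pooled U937 value passed without U937 shLuc replicate 2 (-0.49, limma adjusted p = 0.00963), with a trended and robust prior (0.0260), with array weights (0.0437) and with the dimmest 40% of genes left out (0.0490).

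**Figure D1:**
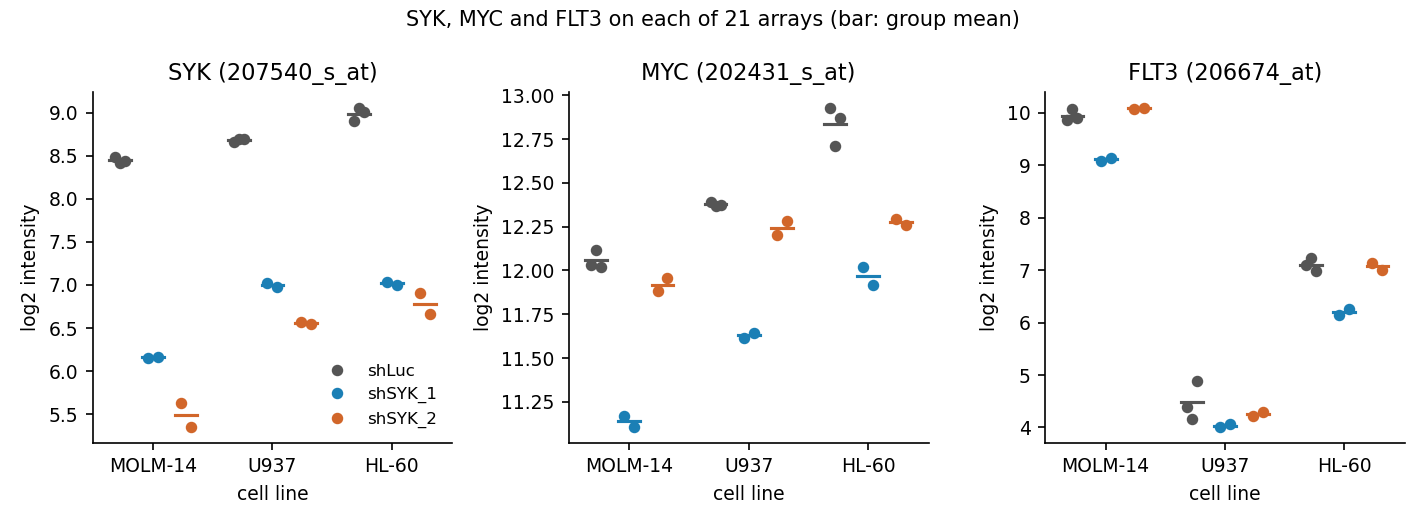
Log2 intensity (vertical axis) of SYK, MYC and FLT3 on each of the 21 arrays, by cell line (horizontal axis) and hairpin (colour), with a bar at each group mean. SYK lay between 5.35 and 7.04 on all SYK hairpin arrays and at 8.42 or above on all shLuc arrays, while FLT3 in MOLM-14 averaged 9.95 with shLuc, 9.11 with shSYK_1 and 10.09 with shSYK_2.

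The first comparison asked which genes responded to SYK knockdown on average over the 3 lines. CD48, a lymphocyte and myeloid surface protein that binds CD244, rose by 1.82 log2 (3.53-fold, SE 0.0392, limma adjusted p = 8.86e-15). LY96, the partner of TLR4 in binding lipopolysaccharide, rose by 1.61 (SE 0.0915), and HMOX1, which degrades heme, by 1.47 (SE 0.0768). RFC5, a subunit of the clamp loader of DNA replication, fell by 1.10 on the log2 scale (SE 0.0605, limma adjusted p = 8.22e-10). RPA2, which coats single-stranded DNA, fell by 0.85 (SE 0.0394), and GINS1, part of the replicative helicase, fell by 0.88 (SE 0.0298).

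Among the genes with the same sign in all 6 hairpin effects, the next largest rises were those of the inhibitory IgG receptor FCGR2B (1.41), the adenosine deaminase ADA2 (1.23), the receptors TREM1 (1.21) and TREM2 (1.18), the monocyte chemokine CCL2 (1.19), TMT1A (1.10), CALHM2 (1.04), LY86 (1.04), which pairs with the receptor CD180, and the tryptophan-degrading enzyme TDO2 (1.004, at low intensity). After SYK, the largest falls were those of the immediate early transcription factor EGR1 (-1.12), RFC5, PRRG4 (-1.03), the neuropeptide GAL (-0.99), CTNNAL1 (-0.97) and PARPBP (-0.93), an inhibitor of homologous recombination. GINS1, RPA2, the G protein subunit GNB1 (-0.82), KLHL23 (-0.82) and EDEM3 (-0.82), which acts in the disposal of misfolded glycoproteins, followed. In total 4144 genes were called, 2075 higher and 2069 lower, with a median absolute change of 0.22 log2. Of these, 1444 had the same sign in all 6 hairpin effects (748 higher, 696 lower), 656 were called in one direction in all 3 lines and 78 in all 6 hairpin effects (42 higher, 36 lower). With a minimum absolute change of 0.5 log2, 363 genes were called. With the mean of each gene's probe sets the changes were 0.47 for TMT1A, -0.56 for GAL, -0.53 for GNB1 and -0.37 for KLHL23. Averaged over the lines, EGR1 passed with shSYK_2 (-1.66) and not with shSYK_1 (-0.58, limma adjusted p = 0.122), and of the 6 hairpin effects it was called in 1, MOLM-14 with shSYK_2 (-3.32). TDO2 was at 3.99 with shSYK_1 in U937 and at 0.03 to 0.61 in the other 5 effects.

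The 2 cell cycle lists and the MYC list fell. Of 27 measured genes of G1/S and DNA replication, 25 fell, 0 rose and 2 were not called (25 fell adjusted over the list alone), with a median change of -0.45 and a camera adjusted p of 1.52e-20. Examples were CDC45 (-0.61) and MCM3 (-0.47), both of the replicative helicase, and DTL (-0.71). Of 24 genes of G2/M and mitosis, 21 fell, 0 rose and 3 were not called (21 fell adjusted over the list alone), with a median of -0.24 (camera adjusted p = 6.99e-11). Among them were the mitotic kinase CDK1 (-0.32), the topoisomerase TOP2A (-0.43), BIRC5 (-0.35) and the centromeric histone CENPA (-0.37). Of 31 MYC targets and ribosome biogenesis genes, 25 fell, 0 rose and 6 were not called (26 fell adjusted over the list alone), with a median of -0.16 (camera adjusted p = 9.22e-10). They included UTP20 (-0.47), the polyamine enzyme ODC1 (-0.38), MRTO4 (-0.30) and CDK4 (-0.27).

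Lists of mature myeloid cells, lysosomes, interferon response and antigen presentation rose. Of 27 monocyte and macrophage genes, 21 rose, 1 fell and 5 were not called (21 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 7.59e-14). CD36, a scavenger receptor, rose by 1.63, the integrin ITGAM by 0.97, the IgG receptor FCGR2A by 0.69 and the protease CTSS by 0.66, while IRF8, a transcription factor of the monocyte lineage named here after its value was seen, fell by 0.51. Of 19 late neutrophil maturation genes, 11 rose, 0 fell and 8 were not called (13 rose adjusted over the list alone), with a median of 0.18 (camera adjusted p = 8.98e-06). Among them were CYBB (0.92) of the oxidative burst, CAMP (0.86), FPR1 (0.74) and HP (0.97). The other 2 probe sets of HP were called in the opposite direction, and with the mean of its probe sets HP did not pass (0.10, limma adjusted p = 0.0885). Of 20 lysosome and autophagy genes, 15 rose, 1 fell and 4 were not called (16 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 1.30e-08). They included the proton pump subunit ATP6V0D1 (0.60), NEU1 (0.58), CTSA (0.50) and PSAP (0.46). Of 27 interferon response genes, 12 rose, 2 fell and 13 were not called (14 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 5.23e-04). The risers included IFI6 (0.81), IRF9 (0.69), IFIH1 (0.52) and ISG15 (0.37). Of 19 antigen presentation genes, 11 rose, 0 fell and 8 were not called (12 rose adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00123). Examples were HLA-DMA (0.55), HLA-DRA (0.42) and the immunoproteasome subunits PSMB9 (0.35) and PSMB8 (0.25). ITGAM changed by 0.45, CYBB by 0.43, FPR1 by 0.38 and IFIH1 by 0.25 with the mean of each gene's probe sets. The 3 falling and 5 rising lists all held with an estimated correlation (camera adjusted p of 8.57e-04 to 0.00806). With shSYK_1 averaged over the lines, the G2/M list (median -0.05, camera adjusted p = 0.632) and the antigen presentation list (0.02, 0.290) did not pass, nor did TOP2A (-0.04) and HLA-DRA (-0.09).

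Another 3 lists were called with the preset correlation alone. Of 17 p53 targets, 8 rose, 1 fell and 8 were not called (8 and 1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0276, adjusted p = 0.163 with an estimated correlation). The death receptor TNFRSF10B (0.35), ZMAT3 (0.34), BAX (0.25) and CCNG1 (0.18) rose, although TNFRSF10B did not pass with the mean of its probe sets (0.13, limma adjusted p = 0.0529). Of 11 primary granule genes, 2 rose, 6 fell and 3 were not called (3 and 6 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.0276, adjusted p = 0.163 with an estimated correlation). The granule proteins PRTN3 (-0.63), MPO (-0.49), AZU1 (-0.36) and CST7 (-0.25) fell. Of 22 oxidative phosphorylation genes, 7 rose, 1 fell and 14 were not called (7 and 1 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.0496, adjusted p = 0.0751 with an estimated correlation). NDUFB5 (0.27), NDUFA1 (0.16) and COX5B (0.15) rose and SDHA (-0.26) fell. Averaged over the lines, the p53 and primary granule lists passed with neither hairpin alone (camera adjusted p of 0.0551 to 0.302). Oxidative phosphorylation passed with shSYK_1 (median 0.18, camera adjusted p = 6.24e-06) and not with shSYK_2 (-0.05, 0.109), and ZMAT3, AZU1, CST7, NDUFA1 and COX5B also passed with shSYK_1 and not with shSYK_2. The oxidative phosphorylation call was lost with each array centred on its median and without any 1 of 15 single arrays, where camera gave adjusted p of 0.0509 to 0.0696. This call and that of the primary granule list were also lost with the dimmest 40% of genes left out (camera adjusted p = 0.0589 and 0.0961) and with HL-60 shSYK_2 replicate 1 placed in shSYK_1 (0.135 and 0.124).

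The remaining lists were not called for the average. Among 28 SYK signalling components, 11 rose, 3 fell and 14 were not called (12 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.0608). Those that fell include SYK itself, the target of the hairpins, and FLT3. Among 20 STAT5 targets, 5 rose, 4 fell and 11 were not called (5 and 4 adjusted over the list alone, median 0.00, mean -0.03 and a test in the negative direction, camera adjusted p = 0.912). The ERK feedback and immediate early list counted 2 up, 5 down and 15 not called of 22 (2 and 5 adjusted over the list alone, median -0.10, camera adjusted p = 0.293). Sterol biosynthesis counted 3 up, 8 down and 6 not called of 17 (3 and 10 adjusted over the list alone, median -0.10, camera adjusted p = 0.0608). The ATF4 amino acid response counted 2 up, 5 down and 15 not called of 22 (2 and 5 adjusted over the list alone, median -0.05, camera adjusted p = 0.192). For HOXA and stem-like genes the counts were 1 up, 5 down and 9 not called of 15 (1 and 6 adjusted over the list alone, median -0.08, camera adjusted p = 0.0772). NF-kB inflammatory genes counted 8 up, 3 down and 11 not called of 22 (8 and 4 adjusted over the list alone, median 0.07, camera adjusted p = 0.0968). In the BCL2 family, 8 rose, 6 fell and 2 were not called of 16 (8 and 6 adjusted over the list alone, median 0.13, camera adjusted p = 0.749).

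Glycolysis genes counted 4 up, 2 down and 12 not called of 18 (4 and 2 adjusted over the list alone, camera adjusted p = 0.749), with a median of -0.04 and a mean of 0.06, so that the median and the test differed in sign. Of 24 ribosomal protein genes 2 rose, 0 fell and 22 were not called (0 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.183). Markers of other cell types gave 0 called of 11 erythroid genes (median 0.02, camera adjusted p = 0.844) and 0 of 8 B cell genes (median 0.01 with a test in the negative direction, camera adjusted p = 0.996), with 0 in both adjusted over the list alone. Of 11 megakaryocyte genes 0 rose and 1 fell (the same adjusted over the list alone, median 0.05 with a test in the negative direction, camera adjusted p = 0.912). Of 13 T and NK cell genes 1 rose and 2 fell (the same adjusted over the list alone, median -0.04, camera adjusted p = 0.61). Of 14 epithelial and stromal genes 1 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.03, camera adjusted p = 0.671).

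**Figure D2:**
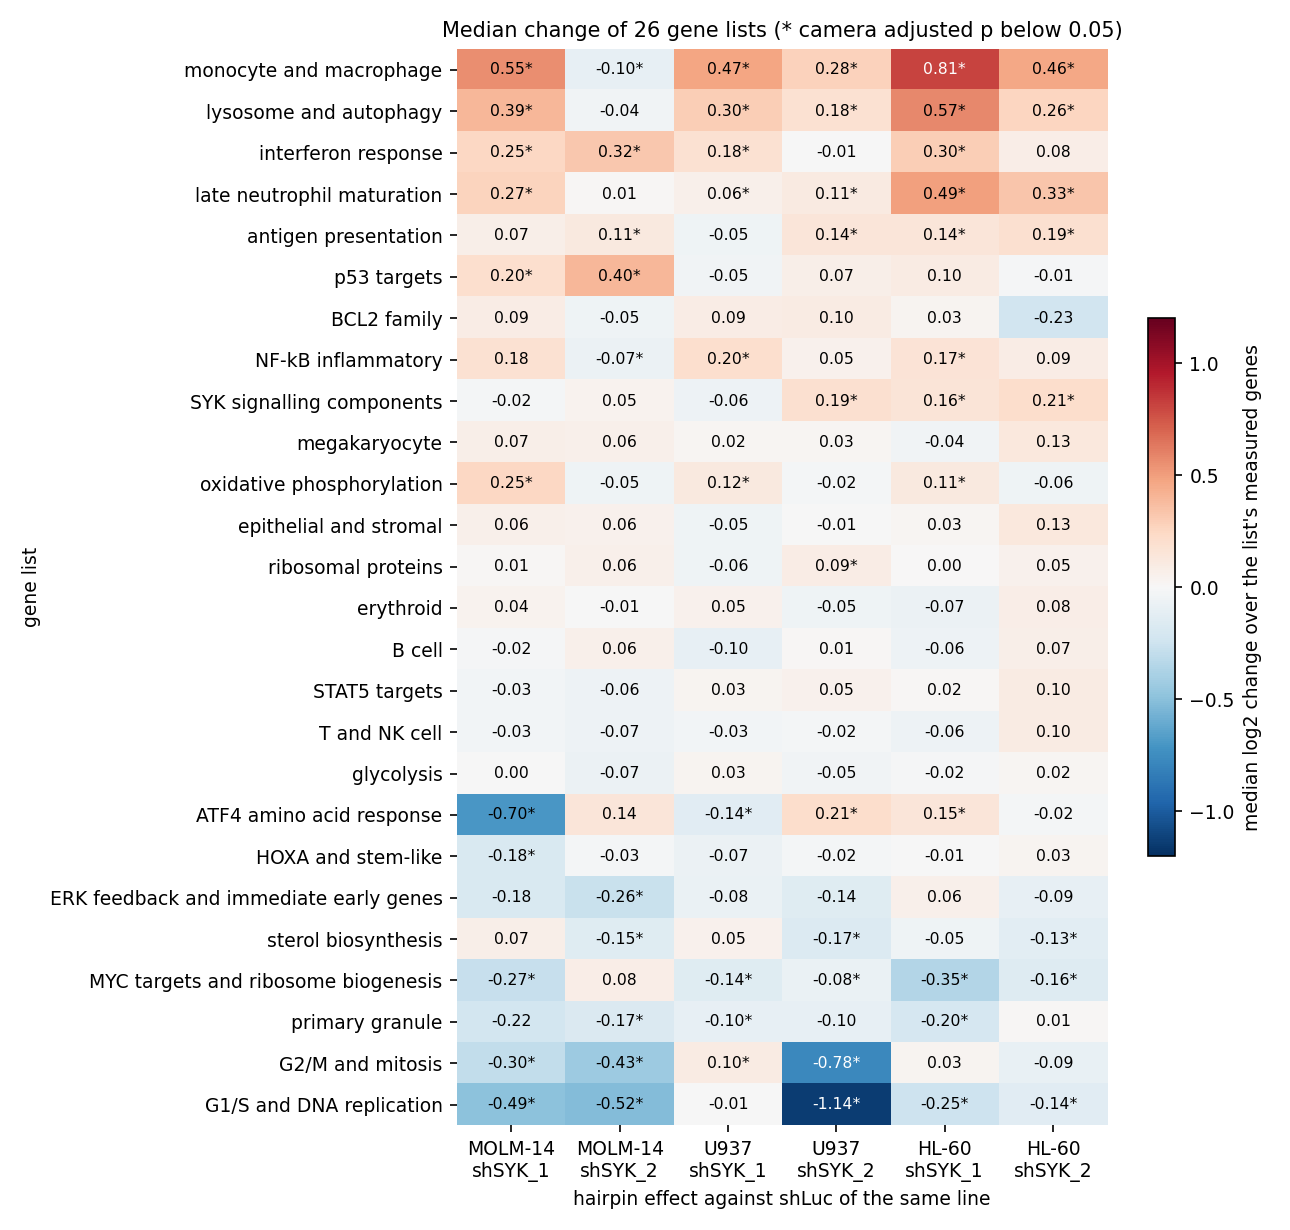
Median log2 change (colour and number) of each of the 26 gene lists (vertical axis) for each hairpin against shLuc in each line (horizontal axis), with a star where camera gave an adjusted p below 0.05. The monocyte and macrophage list had medians of 0.28 to 0.81 in 5 hairpin effects and of -0.10 in MOLM-14 with shSYK_2, and the G1/S list ranged from -0.01 to -1.14 between the hairpins in U937.

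In MOLM-14, CD48 rose most, by 2.29 log2 (4.88-fold, SE 0.0679, limma adjusted p = 1.47e-12), followed by TREM2 (1.80, SE 0.181), a lipid-sensing receptor of macrophages. The germline cyclin CCNA1 (1.46), the pattern recognition protein PTX3 (1.43), the ISG15-conjugating enzyme UBE2L6 (1.39), the NADPH oxidase subunit CYBB (1.33), HMOX1 (1.31) and ADA2 (1.20) rose as well, as did CSRP3 (1.42) and FAP (1.33), both at low intensity. EGR1 fell by 2.19 on the log2 scale (SE 0.403, limma adjusted p = 9.36e-04), and ALDH1A3, which makes retinoic acid, fell by 1.72 (SE 0.138). PRRG4 (-1.45), MS4A4A (-1.45), the transcriptional regulator ID1 (-1.45), RFC5 (-1.23), the RAP activator RASGRP2 (-1.15) and, at low intensity, the receptors IL7R (-1.42) and FGFR3 (-1.36) fell too. TREM2, CCNA1, FAP and CYBB were at 2.70, 2.32, 2.60 and 2.66 with shSYK_1 and at 0.89, 0.61, 0.07 and 0.01 with shSYK_2, while EGR1 was at -3.32 with shSYK_2 and did not pass with shSYK_1 (-1.06, limma adjusted p = 0.129). In all, 2361 genes were called, 1207 higher and 1154 lower. CYBB changed by 0.58, ALDH1A3 by -0.59, FGFR3 by -0.70 and RASGRP2 by -0.56 with the mean of each gene's probe sets.

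Both cell cycle lists fell almost throughout in MOLM-14. Of 27 G1/S genes 26 fell and 1 was not called (26 adjusted over the list alone, median -0.50, camera adjusted p = 2.97e-26), including the nucleotide enzyme TYMS (-0.67). Of 24 G2/M genes 23 fell and 1 was not called (24 adjusted over the list alone, median -0.35, camera adjusted p = 1.12e-16), including the kinase AURKB (-0.43). Of 27 interferon response genes 12 rose, 1 fell and 14 were not called (13 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 5.66e-05), with IFI6 at 1.08 and CXCL10 at 0.84 (low intensity). Of 27 monocyte genes 12 rose, 1 fell and 14 were not called (13 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 3.60e-04), with CD163 at 0.56 (low intensity) and IRF8 at -0.70. Of 17 p53 targets 9 rose, 1 fell and 7 were not called (10 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 2.18e-04), including the DNA repair genes XPC (0.40) and DDB2 (0.41) and ZMAT3 (0.67). Of 22 oxidative phosphorylation genes 6 rose, 1 fell and 15 were not called (8 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0097). The monocyte list rose with shSYK_1 (17 up, 1 down, median 0.55, camera adjusted p = 1.05e-10) and fell with shSYK_2 (1 up, 8 down, median -0.10, camera adjusted p = 0.00428, adjusted p = 0.0761 with an estimated correlation). Oxidative phosphorylation passed with shSYK_1 (median 0.25, camera adjusted p = 4.52e-07) and not with shSYK_2 (-0.05, 0.201). CD163 was at 0.08 with shSYK_2 and CXCL10 at 0.20 with shSYK_1. TYMS changed by -0.20 and CD163 by 0.30 with the mean of each gene's probe sets. Pooled over the hairpins, these 6 lists held with an estimated correlation (camera adjusted p of 0.00271 to 0.0482).

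A further 8 lists were called in MOLM-14 with the preset correlation alone. Of 22 genes of the ATF4 amino acid response 10 fell, 0 rose and 12 were not called (14 fell adjusted over the list alone, median -0.28, camera adjusted p = 3.28e-06, adjusted p = 0.213 with an estimated correlation). The glutathione-degrading enzyme CHAC1 (-1.004) and the amino acid transporter SLC7A5 (-0.63) fell. Of 20 lysosome genes 9 rose, 0 fell and 11 were not called (9 adjusted over the list alone, median 0.24, camera adjusted p = 2.04e-04, adjusted p = 0.0539 with an estimated correlation). Of 31 MYC targets 8 fell, 0 rose and 23 were not called (10 adjusted over the list alone, median -0.10, camera adjusted p = 2.59e-04, adjusted p = 0.0634 with an estimated correlation). Late neutrophil genes counted 3 up, 0 down and 16 not called (3 adjusted over the list alone, median 0.15, camera adjusted p = 0.0271, adjusted p = 0.0539 with an estimated correlation). Antigen presentation counted 4 up, 1 down and 14 not called (5 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.0327, adjusted p = 0.0634 with an estimated correlation). The ERK list counted 1 up, 7 down and 14 not called (2 and 8 adjusted over the list alone, median -0.15, camera adjusted p = 0.0327, adjusted p = 0.338 with an estimated correlation), where the ERK inhibitors SPRY4 (-0.46) and SPRY2 (-0.36) fell and the ERK phosphatase DUSP6 (0.31) rose. Primary granule genes counted 1 up, 4 down and 6 not called (1 and 5 adjusted over the list alone, median -0.11, camera adjusted p = 0.0327, adjusted p = 0.213 with an estimated correlation), with MPO at -0.83 and ELANE at 0.32. HOXA and stem-like genes counted 1 up, 3 down and 11 not called (1 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0344, adjusted p = 0.0643 with an estimated correlation), with CDK6 at -0.73 and BCL2 at -0.71. The ATF4, lysosome, MYC, late neutrophil and HOXA lists passed with shSYK_1 and not with shSYK_2 (camera adjusted p of 0.166 to 0.904), where the ATF4, MYC and lysosome medians were 0.14, 0.08 and -0.04. The ERK, primary granule and antigen presentation lists passed with shSYK_2 and not with shSYK_1 (camera adjusted p of 0.611 to 0.679). CHAC1, SLC7A5 and DUSP6 passed with shSYK_1 alone, and SPRY2 and CDK6 with shSYK_2 alone. Without MOLM-14 shLuc replicate 1 the calls of the ERK (camera adjusted p = 0.171), late neutrophil (0.0714), HOXA (0.0669) and antigen presentation (0.0872) lists were lost. Calls were also lost without MOLM-14 shLuc replicate 2 (HOXA, camera adjusted p = 0.0673) or 3 (primary granule, 0.0556), shSYK_1 replicate 2 (ERK, 0.0603), shSYK_2 replicate 1 (primary granule, 0.0616, and HOXA, 0.0535) and shSYK_2 replicate 2 (antigen presentation, 0.0512). The mean of each gene's probe sets ended the ERK (camera adjusted p = 0.0848), late neutrophil (0.0605) and HOXA (0.0848) calls and gave -0.28 for SPRY4 and -0.42 for BCL2. Leaving out the dimmest 40% of genes ended the ERK (camera adjusted p = 0.129) and primary granule (0.106) calls, and placing HL-60 shSYK_2 replicate 1 in shSYK_1 ended those of the primary granule list (0.0559) and DUSP6 (limma adjusted p = 0.0515).

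In U937, MS4A4A, a membrane protein of macrophages, rose by 2.93 log2 (7.60-fold, SE 0.166, limma adjusted p = 5.98e-09), CD36 by 2.78 (SE 0.141) and LY96 by 2.64 (SE 0.159). TDO2 (2.30, at low intensity), CD48 (2.04), the lipid-binding protein ANXA1 (1.92), FCGR2B (1.87), CCL2 (1.75), the calcium-binding protein S100A8 (1.67) and the ribonuclease RNASE6 (1.63) rose as well. IGLL1, a surrogate light chain of the B cell precursor receptor, fell by 2.66 on the log2 scale (SE 0.245, limma adjusted p = 1.58e-06), at low intensity. CAB39L (-1.83), DNAJC6 (-1.10) and CUX2 (-1.03), also at low intensity, and RFC5 (-1.23), PLAC8 (-1.20), CTNNAL1 (-1.20), RPA2 (-1.13) and ID1 (-1.13) fell. TDO2 and S100A8 were at 3.99 and 3.28 with shSYK_1 and at 0.61 and 0.05 with shSYK_2. Calls were made for 1793 genes, 871 higher and 922 lower, and with HL-60 shSYK_2 replicate 1 placed in shSYK_1, 1121 were called in U937. S100A8 changed by 0.73 and DNAJC6 by -0.57 with the mean of each gene's probe sets.

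Of 27 G1/S genes in U937, 26 fell and 1 was not called (26 adjusted over the list alone, median -0.58, camera adjusted p = 2.65e-29), with DTL at -1.01. Of 24 G2/M genes 20 fell and 4 were not called (23 adjusted over the list alone, median -0.31, camera adjusted p = 8.42e-16), with the spindle protein TPX2 at -0.40. Both falls came with shSYK_2, where the medians were -1.14 (G1/S, camera adjusted p = 3.67e-46) and -0.78 (G2/M, 7.69e-33). With shSYK_1 the G1/S list did not pass (median -0.01, camera adjusted p = 0.822) and the G2/M list rose (6 up, 0 down, median 0.10, camera adjusted p = 0.0233, adjusted p = 0.365 with an estimated correlation). DTL was at -0.28 and TPX2 at 0.09 with shSYK_1, and neither passed. Of 27 monocyte genes 15 rose, 1 fell and 11 were not called (16 and 2 adjusted over the list alone, median 0.46, camera adjusted p = 5.96e-12), with ITGAM at 1.28 and FCGR1A at 0.90. Of 20 lysosome genes 11 rose, 0 fell and 9 were not called (13 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 4.54e-10). Of 19 late neutrophil genes 4 rose, 0 fell and 15 were not called (4 adjusted over the list alone, median 0.08, camera adjusted p = 0.00212), with the antimicrobial peptide CAMP at 1.45. Pooled over the hairpins, these 5 lists held with an estimated correlation (camera adjusted p of 9.71e-04 to 0.0134). The MYC list counted 1 up, 8 down and 22 not called (1 and 11 adjusted over the list alone, median -0.10, camera adjusted p = 2.97e-04, adjusted p = 0.0831 with an estimated correlation), with the transferrin receptor TFRC at 0.51. NF-kB inflammatory genes counted 5 up, 0 down and 17 not called (5 adjusted over the list alone, median 0.11, camera adjusted p = 0.0124, adjusted p = 0.296 with an estimated correlation), including the survival protein BCL2A1 (1.18) and the chemokine CXCL8 (1.38). Primary granule genes counted 0 up, 3 down and 8 not called (0 and 4 adjusted over the list alone, median -0.10, camera adjusted p = 0.0364, adjusted p = 0.242 with an estimated correlation), with AZU1 at -0.54. Interferon response genes counted 7 up, 2 down and 18 not called (8 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.0394, adjusted p = 0.0737 with an estimated correlation), with IFIT1 at 0.87 (low intensity) and IFITM1 at -0.61. The NF-kB, primary granule and interferon lists passed with shSYK_1 and not with shSYK_2 (camera adjusted p of 0.291 to 0.732), as did TFRC, CXCL8, AZU1 and IFIT1. Without U937 shLuc replicate 2 the calls of the primary granule (camera adjusted p = 0.165) and interferon (0.142) lists were lost, as they were without U937 shSYK_2 replicate 1 (0.0638 and 0.0635) and with array weights. The interferon call was also lost without MOLM-14 shLuc replicate 2 (camera adjusted p = 0.0560) and, like the NF-kB call, without U937 shSYK_1 replicate 2 (0.0601 for both). Leaving out the dimmest 40% of genes ended the interferon (camera adjusted p = 0.230) and primary granule (0.102) calls, quantile normalisation ended that of the interferon list (0.0501), and placing HL-60 shSYK_2 replicate 1 in shSYK_1 ended that of the primary granule list (0.117). With the mean of each gene's probe sets the changes were 0.51 for FCGR1A, 0.62 for ITGAM and 0.28 for CXCL8.

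Pooled over both hairpins, HL-60 had the largest number of called genes of the 3 lines, although with shSYK_1 alone MOLM-14 had more (3096 against 2953). OLR1, a receptor for oxidised low-density lipoprotein, rose by 2.71 log2 (6.55-fold, SE 0.137, limma adjusted p = 6.69e-10, at low intensity), and CD14, the lipopolysaccharide co-receptor of monocytes, rose by 2.39 (SE 0.124). The amino acid transporter subunit SLC7A7 (2.27), ANXA2 (2.24), the interleukin-10 receptor IL10RA (2.15), the lipase PLA2G7 (2.03) and the complement component C1QA (1.94), both at low intensity, CD52 (1.89), ADA2 (1.89) and the receptor LPAR6 (1.89) rose too. After SYK, TENT5C, a poly(A) polymerase, fell by 1.52 on the log2 scale (SE 0.140, limma adjusted p = 6.02e-07). PLCB4 (-1.35) and GPM6B (-1.23), both at low intensity, ALDH5A1 (-1.30), the Mediator subunit MED21 (-1.21), ICAM2 (-1.17), the ectoenzyme CD38 (-1.16), ADGRA3 (-1.14) and the G protein regulator RGS16 (-1.11) fell as well. In total 2970 genes were called, 1382 higher and 1588 lower. Models of the HL-60 arrays alone called 1811 genes, and HL-60 shSYK_2 replicate 1 placed in shSYK_1 gave 1696. This array had a mean log2 of 10.4 on the bacterial hybridisation controls, against 8.15 to 8.81 on the other 20 arrays. ALDH5A1 changed by -0.70 and GPM6B by -0.74 with the mean of each gene's probe sets. MED21 fell with shSYK_2 (-2.30) and was at -0.12 with shSYK_1, and OLR1 was at 4.09 with shSYK_1 and 1.33 with shSYK_2.

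Of 27 monocyte genes in HL-60, 21 rose, 1 fell and 5 were not called (22 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 1.42e-15), with the beta-glucan receptor CLEC7A at 1.86 (low intensity) and CTSB at 0.89. Of 31 MYC targets 26 fell, 0 rose and 5 were not called (28 adjusted over the list alone, median -0.29, camera adjusted p = 7.32e-13), with BOP1 at -0.55. Of 20 lysosome genes 13 rose, 0 fell and 7 were not called (13 adjusted over the list alone, median 0.46, camera adjusted p = 1.11e-07), including WIPI1 (1.01) and TFEB (0.81), a transcription factor of lysosomal genes. Of 19 late neutrophil genes 11 rose, 0 fell and 8 were not called (14 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 1.32e-06), with FPR1 at 1.24 and PADI4 at 1.36 (low intensity). Of 19 antigen presentation genes 9 rose, 1 fell and 9 were not called (9 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 5.27e-04). Of 28 SYK signalling components 13 rose, 2 fell and 13 were not called (14 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 6.78e-04), where FCER1G (1.17), an adaptor that recruits SYK, the kinase FGR (0.94) and the integrin ITGB2 (0.53) rose. Those that fell were SYK itself and FLT3. Of 27 interferon response genes 8 rose, 1 fell and 18 were not called (8 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.0113). BOP1 changed by -0.28, WIPI1 by 0.66, FPR1 by 0.68 and PADI4 by 0.89 with the mean of each gene's probe sets. Pooled over the hairpins, these 7 lists held with an estimated correlation (camera adjusted p of 4.35e-04 to 0.0244). The interferon list passed with shSYK_1 and not with shSYK_2 (median 0.08, camera adjusted p = 0.393).

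Of 27 G1/S genes in HL-60, 14 fell, 1 rose and 12 were not called (17 and 1 adjusted over the list alone, median -0.21, camera adjusted p = 9.32e-06, adjusted p = 0.103 with an estimated correlation), with GINS1 at -0.77 and MCM10 at -0.54. Sterol biosynthesis genes counted 1 up, 6 down and 10 not called (1 and 6 adjusted over the list alone, median -0.11, camera adjusted p = 0.0376, adjusted p = 0.194 with an estimated correlation), with the lanosterol synthase LSS at -0.63. NF-kB inflammatory genes counted 7 up, 3 down and 12 not called (7 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 0.0399, adjusted p = 0.518 with an estimated correlation), with the cytokine IL1B at 1.16 and NFKBIA, an NF-kB inhibitor, at 0.49. The sterol list did not pass with shSYK_1 (median -0.05, camera adjusted p = 0.316), nor the NF-kB list with shSYK_2 (0.09, 0.353). The sterol call was lost after quantile normalisation and without HL-60 shLuc replicate 2 (camera adjusted p = 0.0563), HL-60 shSYK_1 replicate 2 (0.0766) or HL-60 shSYK_2 replicate 2 (0.0558). The NF-kB call was lost without HL-60 shLuc replicate 2 (camera adjusted p = 0.0777), HL-60 shSYK_1 replicate 1 (0.0732) or HL-60 shSYK_2 replicate 2 (0.193). Both were lost with the dimmest 40% of genes left out (camera adjusted p = 0.117 and 0.120), and with the mean of its probe sets LSS changed by -0.38.

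Whether the response differed between MOLM-14 and the other lines was tested as the MOLM-14 log2 change minus the mean of the U937 and HL-60 changes. Both hairpins were pooled, and no limma test of this difference was made for each hairpin alone. The most negative difference was that of the macrophage gene MS4A4A, which differed by -2.85 (SE 0.203, limma adjusted p = 4.64e-07), falling in MOLM-14 and rising in U937. FCER1G, an adaptor of Fc receptors, differed by -1.76 (SE 0.0757), SLC7A7 by -1.74 (SE 0.109), CD36 by -1.72 (SE 0.172), the chemokine receptor CCR1 by -1.65 (SE 0.0704), ALDH1A3 by -1.65 (SE 0.169), the co-receptor NRP1 by -1.64 (SE 0.150) and CXCL8 by -1.61 (SE 0.370). The most positive differences were those of CCNA1 (1.59, SE 0.0860), IGLL1 (1.54, SE 0.300), which fell in U937, the cadherin FAT1 (1.42), CSRP3 (1.40), PTX3 (1.38), UBE2L6 (1.20), PRSS12 (1.19) and FAP (1.03). With shLuc, ALDH1A3 lay at 3.14 in U937 and 3.36 in HL-60, IGLL1 at 3.07 in MOLM-14, CSRP3 at 2.78 in U937 and 2.73 in HL-60 and MS4A4A at 2.58 in HL-60, near the lowest intensities. FAT1 in U937 (3.20), PRSS12 in HL-60 (3.20) and FAP in all 3 lines (2.92 to 3.31) were as low. A fall cannot be seen from such levels, so the sizes and order of these differences are limited by the floor. SYK differed by -0.63 (SE 0.0837, limma adjusted p = 2.26e-04) on the brighter probe set and by -0.05 (limma adjusted p = 0.834 over all probe sets) on the other. A difference was called for 743 genes, 353 positive and 390 negative. Without single arrays the count fell to 475 (MOLM-14 shSYK_2 replicate 1), 480 (MOLM-14 shLuc replicate 1) and 489 (MOLM-14 shSYK_2 replicate 2), and with HL-60 shSYK_2 replicate 1 placed in shSYK_1 it was 317 and the calls of CD36 (-1.57, limma adjusted p = 0.0557) and PTX3 (1.47, 0.0811) were lost. With the mean of each gene's probe sets the differences were -0.34 for SYK (limma adjusted p = 0.0133), -0.58 for ALDH1A3, -0.72 for NRP1 and -0.36 for CXCL8.

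The list difference was negative for monocyte genes, SYK signalling components and mitotic genes, and these 3 held with an estimated correlation (camera adjusted p of 8.48e-04 to 0.0295). Of 27 monocyte genes 14 had a lower and 1 a higher response in MOLM-14 and 12 were not called (16 and 1 adjusted over the list alone, median -0.32, camera adjusted p = 1.41e-13), with the costimulatory protein CD86 at -1.41, S100A8 at -0.98 and CTSB at -0.53. The median difference was -0.13 with shSYK_1 alone (14 of 27 members negative) and -0.49 with shSYK_2 alone (26 of 27). In MOLM-14, S100A8 was higher than with shLuc with shSYK_1 and lower with shSYK_2. Of 28 SYK signalling components 9 had a lower and 1 a higher response and 18 were not called (10 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 6.21e-06), among them the adaptor BLNK (-0.94, at low intensity in HL-60) and FGR (-0.93). The lower members include SYK itself (-0.63 on the brighter probe set, -0.05 on the other), so the list result restates the knockdown in part. It was not tested without SYK. Of 24 mitotic genes 4 had a lower and 0 a higher response and 20 were not called (13 lower adjusted over the list alone, median -0.21, camera adjusted p = 5.18e-09), with CENPA at -0.34 and AURKB at -0.28. Without MOLM-14 shLuc replicate 1, DLGAP5 (limma adjusted p = 0.0817) and CDK1 (0.115) lost their calls together with CENPA. AURKB lost its call without MOLM-14 shLuc replicate 2 (limma adjusted p = 0.0656) or shSYK_2 replicate 2 (0.0640). CENPA lost its call without MOLM-14 shLuc replicate 1 (limma adjusted p = 0.105) or 3 (0.0622), shSYK_1 replicate 1 (0.0683), shSYK_2 replicate 1 (0.0688) or 2 (0.0598), or U937 shLuc replicate 3 (0.0517). With the mean of each gene's probe sets S100A8 (-0.36, limma adjusted p = 0.119) and CENPA (-0.23, 0.135) did not pass and CD86 differed by -0.81. With HL-60 shSYK_2 replicate 1 placed in shSYK_1, AURKB (limma adjusted p = 0.0536) and CENPA (0.0700) did not pass.

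Another 9 lists differed between MOLM-14 and the other lines with the preset correlation alone. Of 22 ATF4 genes 6 were lower, 0 higher and 16 not called (15 lower adjusted over the list alone, median -0.29, camera adjusted p = 1.07e-10, adjusted p = 0.124 with an estimated correlation), including CHAC1 (-0.96, at low intensity in HL-60). G1/S genes counted 0 higher, 2 lower and 25 not called (2 lower adjusted over the list alone, median -0.13, camera adjusted p = 2.88e-05, adjusted p = 0.124 with an estimated correlation). Both lower genes, RRM2 (limma adjusted p = 0.0572) and TK1 (0.130), lost their calls without MOLM-14 shLuc replicate 1. NF-kB genes counted 0 higher, 5 lower and 17 not called (1 and 10 adjusted over the list alone, median -0.19, camera adjusted p = 7.51e-04, adjusted p = 0.187 with an estimated correlation), with CCL2 at -1.34 and IL1B at -0.85. Of 17 p53 targets 5 were higher, 1 lower and 11 not called (9 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.00119, adjusted p = 0.0901 with an estimated correlation), with DDB2 at 0.41, XPC at 0.36 and the cell cycle inhibitor CDKN1A at -0.60. Lysosome genes counted 0 higher, 2 lower and 18 not called (7 lower adjusted over the list alone, median -0.09, camera adjusted p = 0.00542, adjusted p = 0.14 with an estimated correlation). Late neutrophil genes counted 1 higher, 5 lower and 13 not called (2 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.0153, adjusted p = 0.0681 with an estimated correlation), with FPR1 at -0.89 and CYBB at 0.62. MYC targets counted 4 higher, 0 lower and 27 not called (4 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.0163, adjusted p = 0.218 with an estimated correlation). Of the members called higher, BOP1 (limma adjusted p = 0.0515), NOP16 (0.120) and IMP4 (0.0847) lost their calls without MOLM-14 shLuc replicate 2. The ERK list counted 0 higher, 3 lower and 19 not called (1 and 5 adjusted over the list alone, median -0.07, camera adjusted p = 0.0216, adjusted p = 0.318 with an estimated correlation), with IER3 at -1.09. Interferon response genes counted 2 higher, 1 lower and 24 not called (4 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.0288, adjusted p = 0.0867 with an estimated correlation), with CXCL10 at 0.69, at low intensity, and IRF7 at -0.51. Calls were lost without MOLM-14 shLuc replicate 1 (ERK list, camera adjusted p = 0.141, and CDKN1A, limma adjusted p = 0.0761), shLuc replicate 3 (interferon list, 0.0938), shSYK_1 replicate 2 (ERK list, 0.0609, and CDKN1A, 0.0551) and shSYK_2 replicate 2 (interferon list, 0.0586). The mean of each gene's probe sets ended the calls of CYBB (0.23, limma adjusted p = 0.0820) and of the lysosome list (camera adjusted p = 0.0592) and gave -0.50 for FPR1. Leaving out the dimmest 40% of genes ended the late neutrophil (camera adjusted p = 0.130) and interferon (0.282) calls. Placing HL-60 shSYK_2 replicate 1 in shSYK_1 ended those of the MYC list (camera adjusted p = 0.0686), XPC (limma adjusted p = 0.0825) and IL1B (0.118). The ERK list did not pass the directional fry test (adjusted p = 0.0661), which asks a different question from camera.

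**Figure D3:**
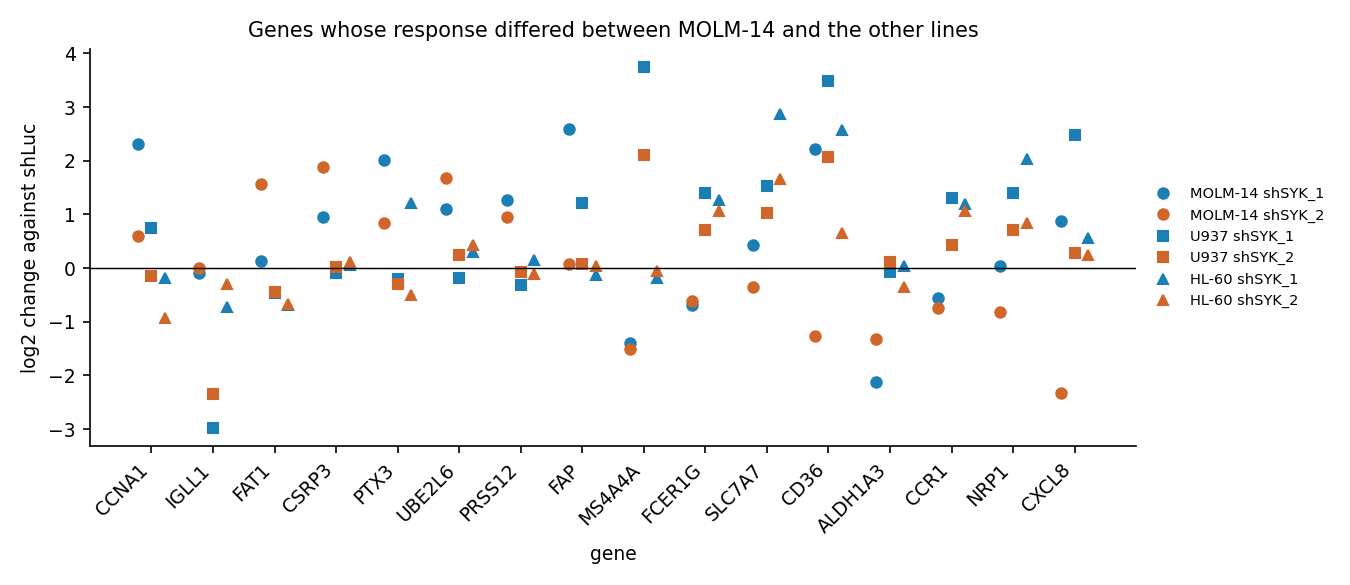
Log2 change against shLuc (vertical axis) of the 8 genes with the most positive and the 8 with the most negative called differences between MOLM-14 and the other lines (horizontal axis), for each hairpin (colour) in each line (symbol). MS4A4A lay at -1.39 and -1.51 in MOLM-14 and at 3.74 and 2.11 in U937, and CD36 lay at 2.23 with shSYK_1 and -1.27 with shSYK_2 in MOLM-14.

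The 2 SYK hairpins were compared with each other to see which changes depended on the hairpin used. The calcium-binding protein S100A8 differed by -2.46 (SE 0.0747, limma adjusted p = 2.03e-12), its partner S100A9 by -2.01 (SE 0.0804), CD36 by -2.28 (SE 0.106), CXCL8 by -1.91 (SE 0.228), CD86 by -1.78 (SE 0.103) and SNX10 by -1.74 (SE 0.0640). MED21 (-2.28) and the cyclin CCNE2 (-2.14) were lower with shSYK_2 too, and MED21 changed by -2.07, -2.37 and -2.30 with shSYK_2 in MOLM-14, U937 and HL-60 against 0.10, 0.10 and -0.12 with shSYK_1. NFU1, an iron-sulfur cluster protein, differed by 1.77 (SE 0.0418, limma adjusted p = 7.68e-14), with changes of -1.61, -1.44 and -1.64 with shSYK_1 and 0.18, 0.34 and 0.11 with shSYK_2. MLC1 (1.66), the histone H2AC6 (1.58), the heme synthesis enzyme UROS (1.57), JADE3 (1.46), DYNLT3 (1.43), KRCC1 (1.38) and ITM2C (1.30) were higher with shSYK_2 as well. CXCL8 differed by -0.28 and CD86 by -0.97 with the mean of each gene's probe sets. The difference was called for 4342 genes, 2099 higher and 2243 lower with shSYK_2.

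Among the lists, tested between hairpins after the data had been seen, 6 held with an estimated correlation (camera adjusted p of 0.00196 to 0.0478). The medians were -0.39 for monocyte genes (20 of 27 lower, 1 higher, camera adjusted p = 3.43e-09), -0.37 for mitotic genes (24 of 24 lower, camera adjusted p = 3.88e-14), -0.41 for G1/S genes (20 of 27 lower, camera adjusted p = 6.68e-11), -0.18 for oxidative phosphorylation (16 of 22 lower, camera adjusted p = 6.11e-07), -0.18 for sterol biosynthesis (10 of 17 lower, 1 higher, camera adjusted p = 5.20e-04) and -0.22 for interferon response (10 of 27 lower, 5 higher, camera adjusted p = 0.0177). ATF4 genes were higher with shSYK_2 (16 of 22 higher, 1 lower, median 0.32, camera adjusted p = 2.45e-05, adjusted p = 0.284 with an estimated correlation), as were MYC targets (20 of 31 higher, 1 lower, median 0.18, camera adjusted p = 9.18e-05, adjusted p = 0.0632 with an estimated correlation). NF-kB genes (10 of 22 lower, 2 higher, median -0.16, camera adjusted p = 0.00848, adjusted p = 0.294 with an estimated correlation) and lysosome genes (13 of 20 lower, 1 higher, median -0.28, camera adjusted p = 4.32e-04, adjusted p = 0.0725 with an estimated correlation) were lower. Ribosomal protein genes (8 of 24 higher, 0 lower, median 0.06, camera adjusted p = 0.00748, adjusted p = 0.108 with an estimated correlation) and antigen presentation genes (8 of 19 higher, 1 lower, median 0.14, camera adjusted p = 0.0411, adjusted p = 0.0785 with an estimated correlation) were higher. In U937 the G1/S median was -0.01 with shSYK_1 and -1.14 with shSYK_2, and CDC45 changed by 0.08 and -1.52. In MOLM-14 the monocyte median was 0.55 with shSYK_1 and -0.10 with shSYK_2, where S100A8 changed by 1.87 and -1.69.

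Against shLuc, shSYK_1 called 3096 genes in MOLM-14, 2056 in U937 and 2953 in HL-60, and shSYK_2 called 2018, 1976 and 2611. Both hairpins changed 685 genes in one direction in MOLM-14 (356 higher, 134 expected of independent lists, and 329 lower, 123 expected) and 306 in opposite directions (257 expected). In U937 the counts were 310 higher (86.4 expected), 175 lower (80.7 expected) and 202 opposite (167 expected), and in HL-60 618 higher (153 expected), 547 lower (164 expected) and 116 opposite (318 expected). Simulated unchanged groups had 0.05 or fewer limma calls per hairpin on average, so their 0 shared calls set no expectation. At an unadjusted limma p below 0.05, a threshold chosen after the data had been seen, they shared 102, 102 and 101 genes in one direction, against 1228, 979 and 1827 observed. The 3 shLuc arrays of a line cannot be divided into 2 groups of 2, so part of the excess may come from the shared controls. HL-60 shSYK_2 called 1055 genes with array weights, 1116 in a model of the HL-60 arrays, 1248 without its replicate 1 and 516 with that array placed in shSYK_1. MOLM-14 shSYK_2 called 1130 and 1079 genes without its replicate 1 or 2, U937 shSYK_1 called 1289 without its replicate 1, and U937 shSYK_2 called 1225 and 1091 without its replicate 1 or 2. Counts for both hairpins fell to 405 and 389 in MOLM-14 without shSYK_2 replicate 1 or 2, to 317 and 297 in U937 without shSYK_2 replicate 1 or 2, and to 766 in HL-60 without shSYK_2 replicate 1.

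Across genes, which are not independent replicates, the effects of the same hairpin in different lines correlated at a mean r of 0.452 (0.325 to 0.561 over 6 pairs), and those of different hairpins in different lines at 0.176 (-0.0376 to 0.286 over 6 pairs). These pairs share no arrays. Within a line the 2 hairpins correlated at 0.207 in MOLM-14, 0.272 in U937 and 0.509 in HL-60, where shared controls alone gave 0.400, 0.400 and 0.399 in simulation, and 60.8%, 58.2% and 64.7% of genes had the same sign (63.0%, 63.1% and 63.2% in simulation). The covariances were 0.0185, 0.0210 and 0.0517, against about 0.0057 in simulation in each line. The difference between the hairpins correlated between lines at 0.421 on average (0.348 to 0.478 over 3 pairs).

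**Figure D4:**
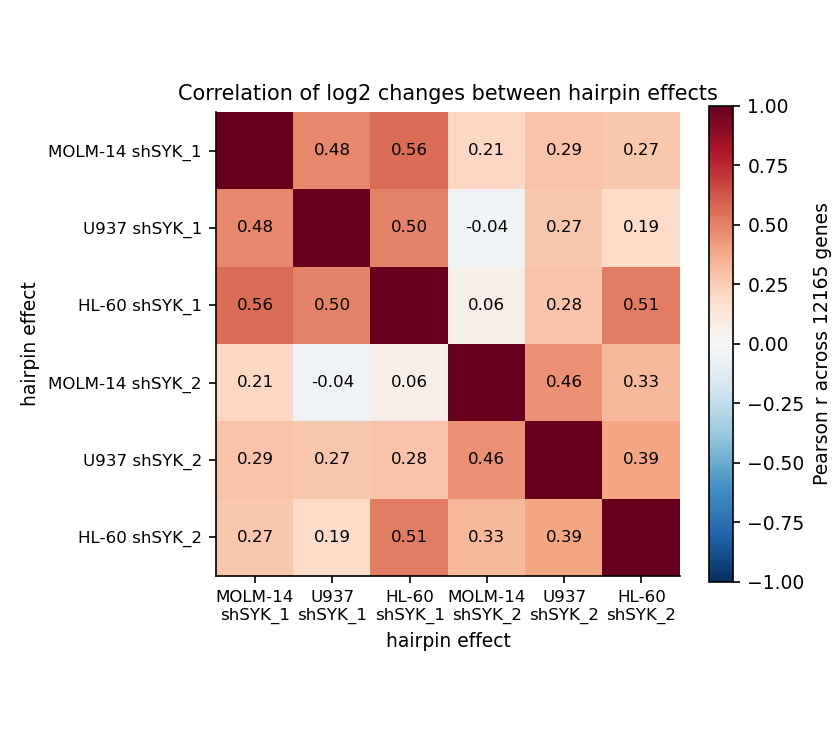
Pearson r across 12165 genes between the log2 changes of each pair of the 6 hairpin effects (both axes), as colour and number. Effects of the same hairpin in different lines ranged from 0.33 to 0.56, and effects of different hairpins in different lines from -0.04 to 0.29.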

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

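All tests of this part were chosen after the result was seen, except the ceiling test and the redrawing of labels, which were fixed earlier.

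A difference between groups was flagged wherever the MOLM-14 change differed from the mean of the U937 and HL-60 changes in a test of the difference itself, which held for 743 genes. SYK (-0.63) differed, and the 8 most positive and 8 most negative differences were those of CCNA1 (1.59), IGLL1 (1.54), FAT1 (1.42), CSRP3 (1.40), PTX3 (1.38), UBE2L6 (1.20), PRSS12 (1.19), FAP (1.03), MS4A4A (-2.85), FCER1G (-1.76), SLC7A7 (-1.74), CD36 (-1.72), ALDH1A3 (-1.65), CCR1 (-1.65), NRP1 (-1.64) and CXCL8 (-1.61). ALDH1A3 in U937 and HL-60, IGLL1 in MOLM-14, CSRP3 in U937 and HL-60, MS4A4A and PRSS12 in HL-60, FAT1 in U937 and FAP in all 3 lines lay near the lowest intensities with shLuc, where a fall cannot be seen, so the sizes of these differences are limited by the floor, and for ALDH1A3 and IGLL1 a difference in response was not shown. The 12 lists that differed in the same test had median differences of -0.13 for SYK signalling components, 0.0723 for MYC targets, -0.0699 for ERK feedback and immediate early genes, -0.29 for the ATF4 amino acid response, 0.30 for p53 targets, -0.32 for monocyte and macrophage genes, -0.0651 for late neutrophil maturation, -0.13 for G1/S, -0.21 for G2/M, 0.21 for interferon response, -0.19 for NF-kB inflammatory genes and -0.0904 for lysosome and autophagy.

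The 2 SYK hairpins gave different responses in the same cells, and 3 explanations were weighed. Deeper SYK knockdown by shSYK_2 would give larger changes of the same sign, but at most 13.1% of the genes called between hairpins in a line had that form, so it is excluded as the main source. The 1 HL-60 array with high hybridisation controls is excluded as well, since 4189 genes were called between hairpins without it, against 4342 with it. Hairpin-specific effects outside SYK predict the same difference in every line, and its lowest correlation between 2 lines was 0.348. The data are consistent with such effects, although a response that changes direction with the depth of knockdown would give the same correlation if it arose in HL-60 from SYK differences of -0.24 and 0.11 on the 2 probe sets.

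The monocyte and macrophage list rose less in MOLM-14 than in U937 and HL-60, and 3 explanations were weighed. A ceiling from higher control levels could not be excluded: over the 13 of 27 members with no higher control level in MOLM-14 the median difference was -0.11 (95% interval -0.53 to -0.01). Weaker SYK knockdown in MOLM-14 is excluded on the brighter probe set alone, where SYK differed by -0.63 (range -0.79 to -0.46, built from its SE) in the other direction. The second SYK probe set differed by -0.05 (SE 0.0854), which does not exclude it, and only RNA was measured here. An effect of shSYK_2 alone could not be excluded: the list differed by -0.13 with shSYK_1 (95% interval -0.30 to 0.09) and by -0.49 with shSYK_2 (95% interval -0.75 to -0.42). The 95% intervals of these list medians came from 10000 resamples of the list's genes and not of the arrays. They treat the genes as independent and do not measure the spread between transductions. A biological difference between the lines, which differ in genotype and lineage, cannot be separated from these with 1 line of each kind.

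A signal outside the main measurement was flagged on HL-60 shSYK_2 replicate 1, where the bacterial hybridisation controls had a mean log2 of 10.4, against 8.15 to 8.81 on the other 20 arrays. One label of this array names shSYK_1, but on 1269 genes that separate the hairpins it lay at 1.05 on a scale from 0 for the HL-60 shSYK_1 mean to 1 for the other shSYK_2 array, which excludes shSYK_1 cells. The HL-60 shLuc arrays lay at 0.824 to 0.838 on this scale. The excess of 1.91 log2 over the mean of the other arrays is consistent with a different hybridisation or a smaller amount of labelled RNA. No biological explanation was tested.

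Labels were redrawn among the 7 arrays of each line, and for the hairpin comparison among the SYK arrays, in 100 splits that include the real one. For gene counts, no other split reached the real one in MOLM-14 (2361, highest other 1613), U937 (1793, highest other 1154) or HL-60 (2970, highest other 2201). The same held for the average (4144, highest other 138) and the hairpin difference (4342, highest other 2656), so chance is excluded for these counts. For the line difference, 2 splits reached the real 743, and the highest other called 863. For list counts, no other split reached the real one in MOLM-14 (14 lists, highest other 12) or the line difference (12 lists, highest other 11). For the average, 4 splits reached the real 11 lists (highest other 11), so chance is unlikely and not excluded. Redrawing within lines removes the response of every line. It cannot tell whether a shared response differs between lines, so chance is not excluded for the line difference. Chance is not excluded for the list counts in U937 (21 splits, 9 lists, highest other 11) and HL-60 (10 splits, 10 lists, highest other 11).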

How the results depend on the processing

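On the probe sets reported, leave-one-out and the other alternatives reversed the direction of no named gene value or list called in either setting. Values called in neither setting were counted as kept whatever their sign. Other probe sets of HP were called in the opposite direction. Of named gene values, 11717 kept their side of the threshold, 231 lost it and 44 gained it (lists 4137, 105 and 43). Without an array of another line, a line's log2 change stays the same. Many values thus could not reverse, so the totals are not independent checks. Camera on single hairpins and their difference and the crossed pairing were chosen after seeing the data. Low intensities limit FLT3 in U937 and genes named as of low intensity. When 1 of 2 arrays of a group is omitted, the lone array is assumed to vary like the other groups. The test for hairpin seed sites in other transcripts was not run. Except where fewer arrays or a stricter threshold lower a count by construction, the cause of the changes below was not tested.

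A minimum absolute change of 0.5 log2 lowered the counts to 363 (average), 544 (MOLM-14), 405 (U937), 775 (HL-60), 309 (line difference) and 864 (hairpin difference), to 169, 139 and 349 for both hairpins in MOLM-14, U937 and HL-60, to 1249, 732 and 1203 with shSYK_1 and to 690, 708 and 887 with shSYK_2. With array weights, HL-60 had 625 genes for both hairpins and 1055 with shSYK_2. A model of the HL-60 arrays alone gave 1811 genes, 540 for both hairpins, 1928 with shSYK_1 and 1116 with shSYK_2. With HL-60 shSYK_2 replicate 1 placed in shSYK_1, 1121 genes were called in U937, 1696 in HL-60 and 317 in the line difference, with 288 for both hairpins in U937, 434 in HL-60 and 516 with HL-60 shSYK_2.

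A fixed block of replicate number gave 1385 genes in MOLM-14, 865 in U937, 1917 in HL-60 and 258 in the line difference, 394, 243 and 671 for both hairpins, and 1224 (MOLM-14 shSYK_2), 1205 (U937 shSYK_1), 1131 (U937 shSYK_2) and 1441 (HL-60 shSYK_2). The block check gave no sign that same-numbered arrays varied together: over 18 same-number pairs the residual correlations were -0.214 to 0.0918, 0 of them over 0.1. In groups of 2 arrays the residuals mirror each other, so each shSYK_1 and shSYK_2 pair entered with the same value for both numbers. The -0.214, from HL-60, would change sign with the numbers crossed, so the check cannot exclude another pairing. With the HL-60 shSYK_2 numbers crossed in this block, the counts were 1539 (MOLM-14), 933 (U937), 264 (line difference), 414, 280 and 711 (both hairpins), 1309 (MOLM-14 shSYK_2), 1308 (U937 shSYK_1), 1223 (U937 shSYK_2) and 1584 (HL-60 shSYK_2).

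With an estimated correlation camera called 6 lists in MOLM-14, 5 in U937 and 3 in the line difference. The directional fry test called 18 lists for the average, 15 in U937 and 16 in HL-60, and the mixed fry test called 23, 23, 22, 21 and 22 lists for the average, MOLM-14, U937, HL-60 and the line difference.

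With single arrays omitted, counts ranged from 3857 to 4560 (average), 1824 to 2692 (MOLM-14), 1286 to 2081 (U937), 2411 to 3649 (HL-60), 475 to 1031 (line difference) and 3905 to 4757 (hairpin difference). Counts for both hairpins ranged from 389 to 813 in MOLM-14, 297 to 588 in U937 and 766 to 1206 in HL-60. Single hairpins gave 2251 to 3463 and 1079 to 2335 in MOLM-14, 1289 to 2344 and 1091 to 2271 in U937, and 2151 to 3274 and 1248 to 3549 in HL-60, for shSYK_1 and shSYK_2. SYK ranged from -2.69 to -2.56, -1.92 to -1.89 and -2.15 to -2.03 in MOLM-14, U937 and HL-60. Lists called ranged from 10 to 12 (average), 10 to 14 (MOLM-14), 7 to 9 (U937), 8 to 10 (HL-60) and 11 to 12 (line difference).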

Other observations

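The test of this part was chosen after the result was seen, and so were the genes named here.

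Among the 78 genes called in one direction in all 6 hairpin effects, NPC1 (0.43), which exports cholesterol from lysosomes, the glycosidases HEXA (0.36), FUCA1 (0.88) and NEU1 (0.58) and the saposin precursor PSAP (0.46) rose on average over the lines. The quinone reductase NQO1 (0.84), the DNA sensor IFI16 (0.88) and the lectin LGALS3 (0.88) rose as well. The transcription factors IRF8 (-0.51) and TFDP1 (-0.54), the DNA repair genes MRE11 (-0.64) and POLQ (-0.52) and the glutamine transporter SLC1A5 (-0.63) fell.

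In the BCL2 family, the average moved in both directions. The antiapoptotic BCL2 fell by 0.53 on the log2 scale while BCL2A1 (0.97) and MCL1 (0.17) rose. Of the proapoptotic members, BAX (0.25) and BNIP3L (0.40) rose and PMAIP1 (-0.64) and BID (-0.23) fell.

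The hypothesis that p53 targets rose more in MOLM-14 because it is the only line of the 3 with wild-type p53 was put to the list test of the line difference. The median difference was 0.30 and camera gave an adjusted p of 0.00119 with the preset correlation and an adjusted p of 0.0901 with an estimated correlation, so the test leaves the hypothesis open. The list was called up in 2 of 6 hairpin effects, both in MOLM-14. The p53 target CDKN1A went the other way (-0.60, with -0.09 and -0.65 in MOLM-14), a call lost without MOLM-14 shLuc replicate 1 (limma adjusted p = 0.0761) or shSYK_1 replicate 2 (0.0551). With 1 line of each genotype, p53 status cannot be told apart from any other feature of MOLM-14.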
